A study of Mus musculus with 9 samples.

How the data were processed

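RNA was sequenced in 9 libraries of mouse embryonic stem cells: 3 wild type, 3 UTX knockout and 3 labelled MLL4 knockdown libraries, prepared with a TruSeq kit per the labels. The titles name JM8A for wild type and the labelled MLL4 knockdown, and A6 for all 3 UTX knockout libraries. The titles of the labelled MLL4 knockdown carry a further number after JM8A. The labels explain neither A6 nor this number. A difference of line or clone therefore cannot be separated from the perturbation in either comparison with wild type. The authors deposited a table of raw read counts per gene symbol with 1 column per library, and every column matched a library by its title. The tools STAR 2.4 and HTSeq 0.6.1 and the builds mm9 and hg19 are named per the submitters' processing notes, which give no roles. The annotation release, strand setting and filters are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart, and members of families with near-identical copies, such as Zscan4 and the X- and Y-linked pairs, are uncertain.

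The total count per library lay between 18570746 and 23874816, so groups were close in depth. Of 33924 genes in the table, 24396 had at least 1 count, and 14772 passed edgeR's filterByExpr by group and were tested. CPM values were computed here from the deposited counts with TMM factors. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom lay between 6.888 and 61.56. Replicates 1 and 3 were sequenced in lane 2 and replicate 2 in lane 1, per the labels.

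Differences were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on all 9 libraries with a term for group only, two-sided, with Benjamini-Hochberg adjusted p under 0.05 within each comparison. The contrasts were UTX knockout against wild type, labelled MLL4 knockdown against wild type, and labelled MLL4 knockdown against UTX knockout. An exact permutation test of 3 against 3 cannot go below p = 0.1, so none is given. Fold changes are in log2 with the standard error of the fitted contrast, and intervals are at 95%. Gene list tests used camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 31 lists per comparison. With an estimated correlation 0 lists passed in any comparison, with 4, 3 and 1 lists at an unadjusted p under 0.05 in the 3 comparisons. The test fry, which asks whether genes of a list move on balance in a single direction without comparing them with other genes, called 10, 13 and 6. Of the 24 camera calls fry kept 14 and lost 10, and it made 15 others. The lost calls were LIF and STAT3, trophectoderm, imprinted, hypoxia and immediate early in the UTX knockout. They were co-activator, hypoxia and 2-cell-like in the labelled MLL4 knockdown, and hypoxia and 2-cell-like between the perturbed groups.

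The lists covered core, naive and formative pluripotency, LIF and STAT3, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, feeder or fibroblast cells, blood and endothelium, Hox genes, retinoic acid response, Nodal, TGF-beta and BMP, Wnt, FGF and ERK, 2-cell-like, germline, imprinted, MLL3/MLL4 COMPASS, other COMPASS and H3K27 demethylase, p300/CBP co-activator, Polycomb, Y-linked, p53, interferon, hypoxia and glycolysis, cholesterol, unfolded protein, immediate early, extracellular matrix, and S and G2/M genes. The groups, tests, lists, rule for named genes and alternatives were fixed before the data were examined, except where stated. Symbols were matched as written or through older symbols: 13 list genes matched through an older symbol, 10 list entries were absent, and 1271 tested symbols differ from current ones. Named genes were, per comparison with wild type, the targeted genes with Uty, Kmt2c, Kmt2b and Ep300; the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap and whose mean log2 CPM was at least 2, leaving out clone, model, small RNA and pseudogene names; and, from each list, up to 4 members of smallest p and any changed member. The direct comparison took 5 per direction, and genes changed in both comparisons 5 of the same and 5 of opposite direction. Many genes that met these rules are not named, above all changed members of lists. Of the 14 cholesterol genes that rose in the UTX knockout, for example, only Insig1 is. The named list members are therefore a selection from what the rule gives.

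Same-numbered libraries deviated together from their group means: across genes, the correlations of replicates 1, 2 and 3 were 0.415, 0.168 and 0.381 for UTX knockout with wild type, 0.416, 0.182 and 0.238 for labelled MLL4 knockdown with wild type, and 0.467, 0.181 and 0.308 for the perturbed groups. Unlike numbers correlated negatively wherever replicate 1 took part (-0.412 to -0.0853). Between replicates 2 and 3 of different groups the correlations lay from -0.0858 to 0.226, the highest for labelled MLL4 knockdown 2 with UTX knockout 3. The pairing of replicates 2 and 3 by number is therefore less clear than that of replicate 1. The pairing comes from the replicate numbers in the titles, and the fit with this block is given beside a result where it changes a call. The shared wild type libraries were set against 30 simulations of unchanged groups. In these edgeR called 0 genes the same way in both comparisons, with a mean of 152 at an unadjusted p under 0.05. Libraries were drawn independently, with the same dispersion of a gene in all groups. Pairs of wild type libraries differed more (chi-square per degree of freedom 34.24 to 61.56) than pairs of the labelled MLL4 knockdown (6.888 to 14.69). The simulations leave this out.

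Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter or a stricter filter (CPM of at least 5 in 3 libraries), only the libraries of the 2 groups compared, a lane term, lane 2 alone, the replicate block, an adjusted p of 0.01, a minimum fold of 1.5, fry, an estimated correlation, and leaving out each library in turn. Removal of transcript length or GC content trends per library and counts outside chromosomes 4, 8 and Y were chosen after seeing the data, as were the tests by chromosome and the stretch of neighbouring genes on chromosome 4. Chromosomes and transcript lengths came from an annotation matched by symbol for 95.83% and 97.98% of tested genes, with names and neighbour order from the RefSeq table of GRCm38.p6, not of the build mm9, so no coordinates are given. Tested on simulated data with known changes, the fit recovered 16.4, 70.2 and 95.5% of genes changed 1.5-, 2- and 4-fold for UTX knockout against wild type (9 false of 130 calls, 14555 genes), 10.5, 65.7 and 90.9% for labelled MLL4 knockdown against wild type (4 of 115, 14559 genes), and 16.4, 70.2 and 97.0% for the perturbed groups (4 of 126, 14568 genes).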

Results

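Gene expression was measured by RNA sequencing in male mouse embryonic stem cells, pluripotent cells from the early embryo, grown on gelatin with serum and the cytokine LIF. The 9 libraries fell into 3 groups of 3: wild type cells, cells with a knockout of UTX (gene Kdm6a, an X-linked H3K27 demethylase), and cells labelled as carrying a knockdown of MLL4 (gene Kmt2d, an H3K4 methyltransferase of enhancers). The series title places both proteins and the acetyltransferase p300 in a shared network, and the comparisons ask which transcripts differ when UTX is removed or MLL4 is targeted. Total gene counts were 18785719, 23515830 and 22475258 in wild type replicates 1 to 3, 19568494, 23874816 and 22411683 in the UTX knockout, and 18570746, 21963345 and 22531867 in the libraries labelled MLL4 knockdown. Of 33924 genes in the table, 14772 were tested.

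The targeted gene Kdm6a stood at 78.9 CPM ± 18.9 (SD, n = 3) in wild type and 16.4 ± 3.33 in the UTX knockout, a log2 fold change of -2.27 (SE 0.20, adjusted p = 0.000155), with 20.8% of the wild type level remaining. The labels do not say which part of the gene was deleted, so remaining reads can come from exons outside it. In the libraries labelled MLL4 knockdown Kdm6a stood at 107 CPM ± 6.50 (log2 fold change 0.44, SE 0.19, adjusted p = 0.105). Kmt2d, listed under its older symbol Mll2, stood at 82.9 CPM ± 37.9 in wild type, 112 ± 16.7 in the UTX knockout and 72.1 ± 1.21 in the libraries labelled MLL4 knockdown. In the libraries labelled MLL4 knockdown its log2 fold change against wild type was -0.20 (SE 0.27, 95% interval -0.79 to 0.39, adjusted p = 0.624) and did not pass the test. In this fit the targeted transcript does not bear out that label, so directions drawn from those libraries rest on the label. The wild type counts of Kmt2d were spread from 1020 in replicate 2 to 2659 in replicate 3. Without wild type replicate 2 the fold change was -0.51 (adjusted p = 0.0353) and without wild type replicate 3 it was 0.16 (adjusted p = 0.666). With the transcript length trend of each library removed it was -0.51 (adjusted p = 0.0213), and -0.49 (SE 0.09, adjusted p = 0.00169) with the replicate block as well. Against the UTX knockout it was -0.64 (SE 0.27, adjusted p = 0.0987; 0.0376 with the replicate block). The paralog Kmt2c had log2 fold changes of 0.42 (adjusted p = 0.324) in the UTX knockout and 0.52 (adjusted p = 0.181) in the libraries labelled MLL4 knockdown. Kmt2b had 0.05 (adjusted p = 0.87) and 0.40 (adjusted p = 0.100; 0.0274 with the replicate block), and Ep300, which encodes p300, had -0.06 (adjusted p = 0.895) and 0.27 (adjusted p = 0.404). Uty, the Y-linked paralog of Kdm6a, fell from 14.1 CPM ± 3.83 to 0.828 ± 0.0696 in the UTX knockout (log2 fold change -4.07, SE 0.28) and to 0.987 ± 0.228 in the libraries labelled MLL4 knockdown (-3.83, SE 0.28). Kdm6a stood at 107 CPM in the libraries labelled MLL4 knockdown, where Uty was nearly absent. This argues against reads shared with Kdm6a as the source of the wild type level of Uty. Such reads may still make up the 16 to 25 counts of Uty left in those libraries.

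**Figure D1:**
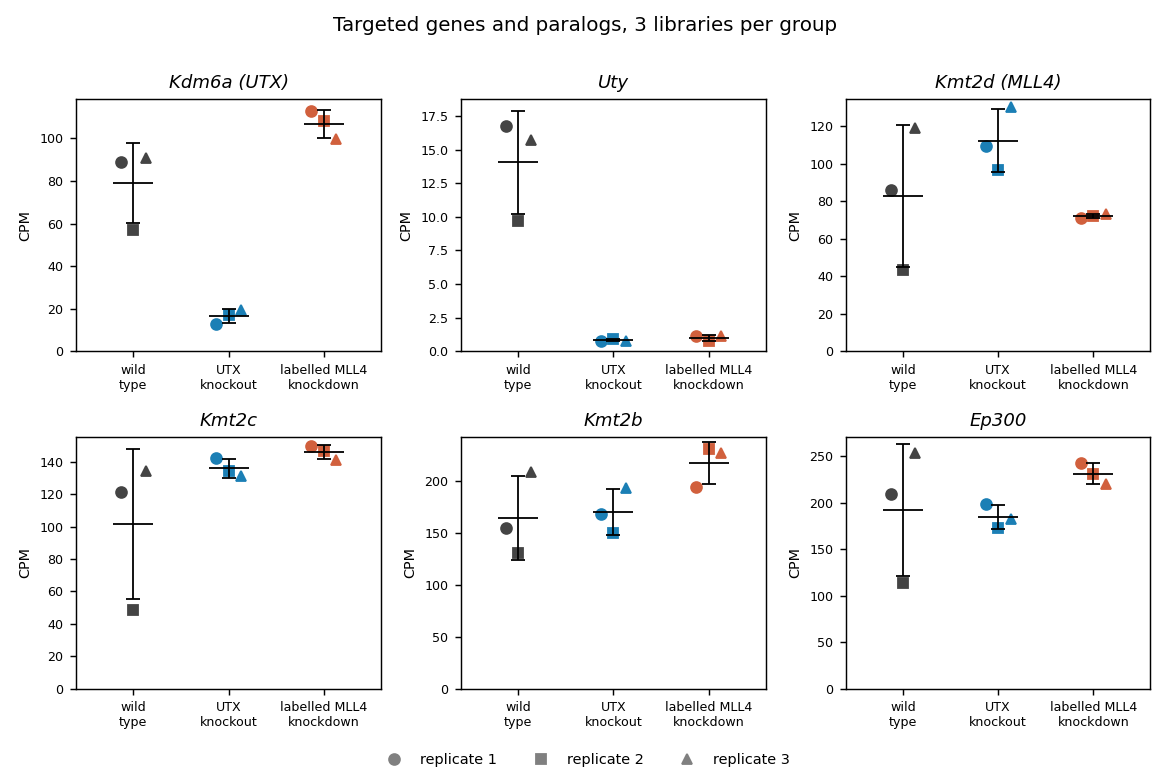
CPM of Kdm6a, Uty, Kmt2d, Kmt2c, Kmt2b and Ep300 in each library (points, shaped by replicate number), with the group mean and SD over 3 libraries (bars). Kdm6a lies at 16.4 CPM in the UTX knockout against 78.9 in wild type, and wild type replicate 2 is the lowest wild type library for each of the 6 genes.

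In the UTX knockout the smooth muscle gene Acta2, the matrix gene Thbs1, the keratin gene Krt8 and the Nodal inhibitor gene Lefty1 were among the largest falls, and the antioxidant gene Gpx2 was among the largest rises. Acta2, smooth muscle actin, fell from 32.9 CPM ± 25.4 to 0.705 ± 0.424 (SD, n = 3; log2 fold change -5.51, SE 0.83), and Thbs1, a secreted matrix glycoprotein, fell from 47.4 ± 34.3 to 1.03 ± 0.388 (-5.50, SE 0.67). Other genes with the largest falls by the fixed rule were Car4 and Car2, carbonic anhydrases (-4.16, SE 0.33 and -3.31, SE 0.39). They also included Lefty1, a secreted Nodal inhibitor (-3.51, SE 0.85), Anxa3, an annexin (-3.48, SE 0.65), and Krt8, a simple-epithelium keratin (-3.40, SE 0.63). Ddx3y, a Y-linked RNA helicase (-3.36, SE 0.32), and Pmp22, a myelin protein (-3.16, SE 0.55), completed the 9 named here. The largest rises were Gpx2, a glutathione peroxidase (2.58, SE 0.37), Nkx6-3, a homeobox factor (2.42, SE 0.54), and Msln, the surface protein mesothelin (2.25, SE 0.53). Dnajb13, a co-chaperone of the sperm flagellum (2.22, SE 0.26), and Lbh, a transcriptional cofactor (2.06, SE 0.44), rose too. A2m, a protease inhibitor (2.03, SE 0.34), Cd68, a lysosomal glycoprotein of macrophages (1.99, SE 0.30), and Pdgfc, a growth factor (1.93, SE 0.17), followed. The last were Rrm2b, a ribonucleotide reductase subunit (1.92, SE 0.20), and Foxn4, a forkhead factor (1.90, SE 0.30). Gpx2 rose from 11.2 CPM ± 1.26 to 67.1 ± 20.1. The highest adjusted p among these 19 genes was 0.019, for Lefty1. Without UTX knockout replicate 2 the calls of Lefty1 (adjusted p = 0.0841), Msln (0.072) and Nkx6-3 (0.0508) ended, and without UTX knockout replicate 3 that of Lefty1 did (0.0785).

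Among signalling and pluripotency lists in the UTX knockout, 10 of 17 Nodal, TGF-beta and BMP targets fell and 0 rose, and 10 and 1 did so adjusted over the list alone. For the Nodal list camera gave adjusted p = 1.93e-05, and adjusted p = 0.242 with an estimated correlation. Lefty2 fell by 3.10 on the log2 scale (SE 0.46), Id3, a BMP target, by 2.43 (SE 0.30), and the matricellular genes Cyr61 and Ctgf by 2.24 (SE 0.11) and 1.77 (SE 0.14). Of 16 genes of formative and primed pluripotency 9 fell and 0 rose, and 10 and 0 did so adjusted over the list alone. For the formative list camera gave adjusted p = 0.000152, and adjusted p = 0.368 with an estimated correlation. The falls included Otx2, a homeobox factor of the formative state (-2.60, SE 0.31), the de novo methyltransferase Dnmt3b (-1.54, SE 0.26) and the POU factor Pou3f1 (-1.14, SE 0.22). Of 15 FGF and ERK targets 4 fell and 0 rose, and 5 and 0 did so adjusted over the list alone. For the FGF and ERK list camera gave adjusted p = 0.0148, and adjusted p = 0.478 with an estimated correlation. The ERK feedback inhibitors Spry2 (-1.23, SE 0.17), Dusp5 (-0.95, SE 0.16) and Dusp6 (-0.74, SE 0.14) were among them, and without wild type replicate 3 the list gave 0.0953. Of 14 LIF and STAT3 targets 4 rose and 0 fell, and 4 and 0 did so adjusted over the list alone. For the LIF and STAT3 list camera gave adjusted p = 0.0105, and adjusted p = 0.529 with an estimated correlation. Tfcp2l1, a naive pluripotency factor listed as Tcfcp2l1, rose by 1.40 (SE 0.24) and Lifr, the LIF receptor, by 0.86 (SE 0.15), and the list gave 0.179 without UTX knockout replicate 3 and 0.354 without wild type replicate 1. Naive pluripotency genes moved both ways, 5 up and 4 down of 20 (7 and 4 adjusted over the list alone, camera adjusted p = 0.0856). With the replicate block camera gave this list an adjusted p of 0.048, directed up, and 0.551 with an estimated correlation. Prdm14, a repressor of differentiation genes, rose by 0.88 (SE 0.15), while Dppa3, a maternal factor of naive cells, and the F-box gene Fbxo15 fell (-1.53, SE 0.20 and -0.77, SE 0.13). Core pluripotency genes had 0 rises and 5 falls of 16 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0718), with L1td1, an RNA-binding protein of stem cells, at -1.31 (SE 0.13) and Lin28a, an inhibitor of let-7 processing, at -0.69 (SE 0.11). Only 2 of these 5 falls were of genes outside chromosomes 4, 8 and Y. In wild type replicate 1 Lefty1 stood at 121 CPM against 21.9 and 17.2 in replicates 2 and 3, Otx2 at 40.8 against 23.5 and 24.5, and Dnmt3b at 523 against 254 and 301.

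Of 15 trophectoderm genes, markers of the outer layer of the blastocyst, 9 fell and 1 rose in the UTX knockout, and 10 and 1 did so adjusted over the list alone. For the trophectoderm list camera gave adjusted p = 0.00457, and adjusted p = 0.599 with an estimated correlation. Krt8 fell by 3.40 (SE 0.63), Krt18 by 3.02 (SE 0.57) and Krt7 by 2.75 (SE 0.58), while Tead4, a factor of the trophoblast lineage, rose by 0.96 (SE 0.28). Its call ended without UTX knockout replicate 1 (adjusted p = 0.0546), 2 (0.111) or 3 (0.0987) and without wild type replicate 1 (0.0525) or 2 (0.0984). Of 13 feeder or fibroblast genes 6 fell and 1 rose, and 7 and 1 did so adjusted over the list alone. For the feeder list camera gave adjusted p = 0.0231, and adjusted p = 0.242 with an estimated correlation. Col6a1, a collagen, fell by 2.96 (SE 0.44) and Tagln, an actin-binding protein of smooth muscle, by 2.62 (SE 0.52), while Fn1, the matrix protein fibronectin, rose by 0.96 (SE 0.21). Of 36 imprinted genes 8 fell and 1 rose, and 8 and 1 did so adjusted over the list alone. For the imprinted list camera gave adjusted p = 0.0253, and adjusted p = 0.444 with an estimated correlation. The noncoding RNA H19 fell by 4.22 (SE 0.41), the growth factor gene Igf2 by 3.21 (SE 0.68) and Snrpn by 0.54 (SE 0.11), while Grb10, an adaptor of insulin signalling, rose by 0.65 (SE 0.13). The wild type libraries themselves differed in these groups: in replicates 1, 2 and 3 Krt8 stood at 19.7, 211 and 170 CPM, Acta2 at 3.84, 50.8 and 43.9, Tagln at 31.2, 158 and 103, and Igf2 at 19.9, 164 and 224. Without wild type replicate 3 the trophectoderm (adjusted p = 0.0652), feeder (0.0568) and imprinted (0.0614) calls ended. With the stricter filter on low counts the trophectoderm and feeder lists both gave 0.372, and the imprinted call also ended without wild type replicate 1 (0.0753) or UTX knockout replicate 2 (0.0658).

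**Figure D2:**
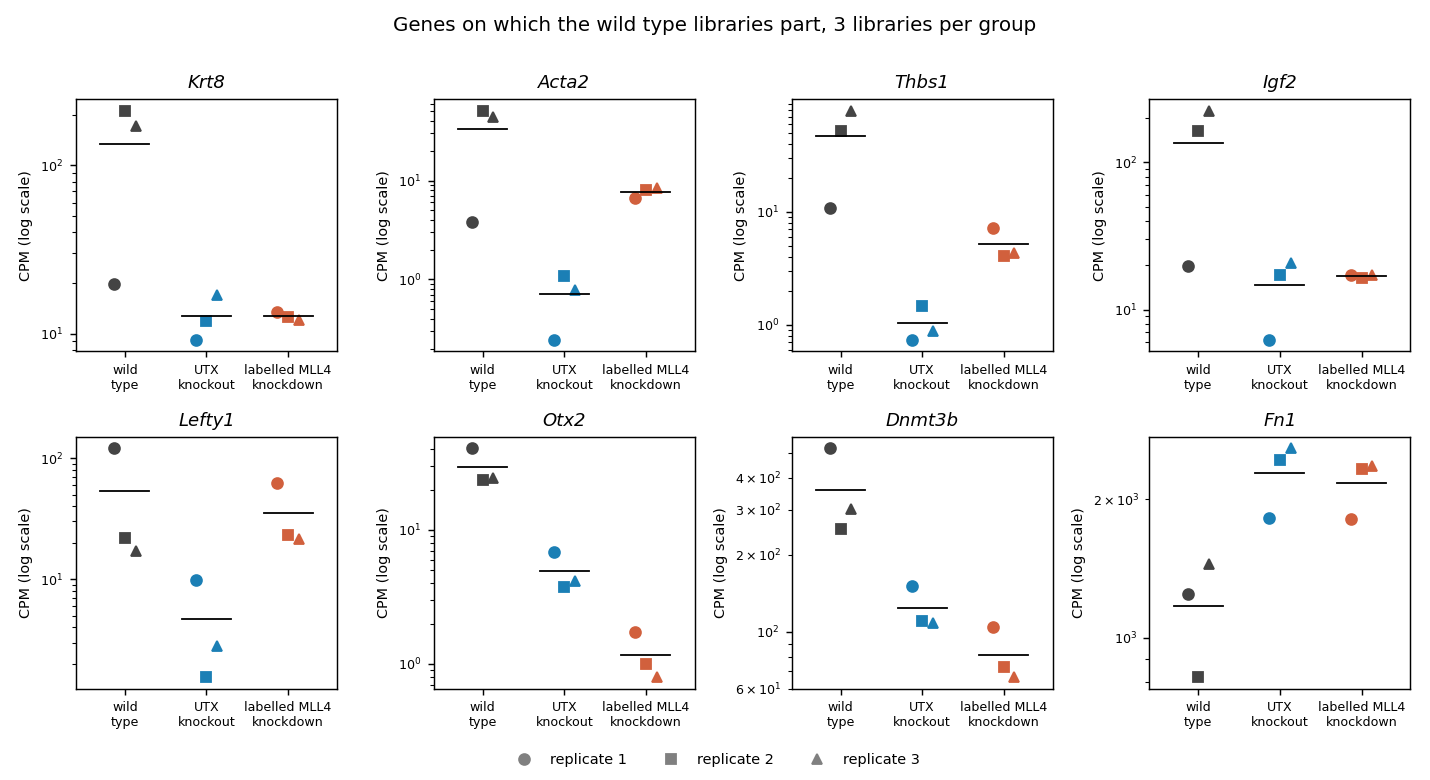
CPM on a log scale of 8 genes in each library (points, shaped by replicate number), Fn1 among them, with the group mean over 3 libraries (bars). Krt8, Acta2, Thbs1 and Igf2 were lower, and Lefty1, Otx2 and Dnmt3b higher, in wild type replicate 1 than in wild type replicates 2 and 3.

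Of 21 genes of cholesterol biosynthesis 14 rose and 0 fell in the UTX knockout, and 15 and 0 did so adjusted over the list alone. For the cholesterol list camera gave adjusted p = 7.77e-08, and adjusted p = 0.242 with an estimated correlation. Insig1, a sterol-sensing retention factor, rose by 1.10 (SE 0.18). Of 11 2-cell-like genes, transcripts of the cleavage embryo that rare stem cells express, 10 fell and 0 rose, and 11 and 0 did so adjusted over the list alone. For the 2-cell-like list camera gave adjusted p = 1.91e-07, and adjusted p = 0.437 with an estimated correlation. Zscan4c fell by 3.10 (SE 0.60) and Zscan4e by 2.90 (SE 0.60), from 8.57, 3.79 and 3.76 CPM of Zscan4c in wild type replicates 1 to 3, and reads shared within this family make single members uncertain. The call of Zscan4e ended without UTX knockout replicate 2 (adjusted p = 0.0548). All 3 measured Y-linked genes fell, and 3 did so adjusted over the list alone. For the Y-linked list camera gave adjusted p = 2.31e-05, and adjusted p = 0.242 with an estimated correlation. Eif2s3y, a translation initiation factor, fell by 3.79 (SE 0.53). Of 15 immediate early genes 6 fell and 0 rose, and 6 and 0 did so adjusted over the list alone. For the immediate early list camera gave adjusted p = 0.0148, and adjusted p = 0.444 with an estimated correlation. It gave 0.0618 without wild type replicate 3 and 0.0835 with the stricter filter on low counts. The stress factor Atf3 fell by 1.58 (SE 0.28), and 4 of the 6 falls were outside chromosomes 4, 8 and Y. Of 25 hypoxia and glycolysis genes 2 rose and 0 fell, and 2 and 0 did so adjusted over the list alone. For the hypoxia list camera gave adjusted p = 0.00315, and adjusted p = 0.62 with an estimated correlation. Both were glycolytic enzymes: Gpi1 rose by 0.86 (SE 0.21) and Aldoc by 1.16 (SE 0.28). The call of Gpi1 ended without UTX knockout replicate 2 (adjusted p = 0.0863) or 3 (0.0648), and that of Aldoc without UTX knockout replicate 2 (0.0853) or 3 (0.0667) or wild type replicate 3 (0.0551).

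Neuroectoderm genes had 0 rises and 4 falls of 12 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0856), with the neuronal tubulin Tubb3 at -1.60 (SE 0.16) and the intermediate filament gene Nes at -1.40 (SE 0.21). Genes of the MLL3/MLL4 COMPASS complex had 3 rises and 1 fall of 10, the fall being Kdm6a (3 and 1 adjusted over the list alone; camera adjusted p = 0.416), with the core subunit Rbbp5 at 0.63 (SE 0.11). Extracellular matrix genes moved both ways, 5 up and 4 down of 23 (7 and 4 adjusted over the list alone; camera adjusted p = 0.493), with the basement membrane genes Nid1 at 1.62 (SE 0.22) and Lama1 at 1.51 (SE 0.17). Blood and endothelium (1 rose and 3 fell of 9; 1 and 3 adjusted over the list alone; adjusted p = 0.273) and germline (2 and 5 of 23; 2 and 5 adjusted over the list alone; 0.148) did not pass the list test. Unfolded protein and amino acid stress (3 and 3 of 20; 3 and 3 adjusted over the list alone; 0.414) and p53 targets (3 and 1 of 19; 3 and 1 adjusted over the list alone; 0.338) did not pass it either.

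In total 2285 genes changed in the UTX knockout, of which 968 rose and 1317 fell, and 262 rose and 595 fell by more than 2-fold. The 3 libraries of one group lay wholly above those of the other for 31.5% of tested genes, against the 10% that chance gives. The replicate block called 3446 genes (1551 up and 1895 down), all 2285 among them, and the libraries of lane 2 alone called 74, with lane 1 holding 1 library per group. Without UTX knockout replicate 2 or 3 the count was 833 or 1100.

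In the libraries labelled MLL4 knockdown, the developmental factors Gli2 and Sall3 and the growth factor gene Pdgfc rose against wild type, and the keratins Krt7, Krt8 and Krt18, the retinoid carrier Crabp2 and the DNA methyltransferase genes Dnmt3a, Dnmt3b and Dnmt3l fell. Emp1, an epithelial membrane protein, rose from 19.9 CPM ± 12.1 to 218 ± 32.0 (SD, n = 3; log2 fold change 3.45, SE 0.48), and Gli2, a transcription factor of Hedgehog signalling, rose from 38.6 ± 9.97 to 220.1 ± 12.0 (2.51, SE 0.19). The other largest rises were Msln (3.64, SE 0.54), Islr2, a neuronal surface protein (2.78, SE 0.37), and Pla2g7, a phospholipase of platelet-activating factor (2.77, SE 0.80). The zinc finger factors Sall3 (2.66, SE 0.19) and Zfp521 (2.55, SE 0.18) and Nkx6-3 (2.62, SE 0.54) also rose, as did Mras, a Ras family GTPase (2.58, SE 0.31), and Pdgfc (2.57, SE 0.18). Otx2 fell from 29.6 CPM ± 9.68 to 1.17 ± 0.487 (-4.67, SE 0.36), and Liph, a lipase, from 28.7 ± 0.766 to 2.00 ± 0.205 (-3.84, SE 0.15). Other largest falls were Krt18 (-3.91, SE 0.60) and Krt7 (-3.88, SE 0.64). Dysf, a membrane repair protein (-3.87, SE 0.37), and Gsn, an actin-severing protein (-3.75, SE 0.38), fell. So did Oas3, an interferon-induced oligoadenylate synthetase (-3.56, SE 0.25), Pla2g1b, a secreted phospholipase (-3.52, SE 0.29), and Arl4c, a small GTPase (-3.40, SE 0.16). The highest adjusted p among these 19 genes was 0.0262, for Pla2g7, whose call ended without replicate 2 (adjusted p = 0.0838) or 3 (0.083) of the labelled MLL4 knockdown or without wild type replicate 3 (0.05, over the threshold before rounding).

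Of 15 trophectoderm genes 12 fell and 1 rose in the libraries labelled MLL4 knockdown, and 12 and 1 did so adjusted over the list alone. For the trophectoderm list camera gave adjusted p = 0.000889, and adjusted p = 0.701 with an estimated correlation. Krt8 fell by 3.40 (SE 0.63), the homeobox gene Esx1 by 3.19 (SE 0.38) and Tfap2c, listed as Tcfap2c, by 1.26 (SE 0.13), while Gata2, a GATA factor of trophoblast and blood, rose by 1.32 (SE 0.32). Over the 15 trophectoderm genes the median log2 CPM above the labelled MLL4 knockdown mean was 0.638, 2.64 and 2.22 in wild type replicates 1, 2 and 3. Of 14 LIF and STAT3 targets 8 rose and 2 fell, and 9 and 2 did so adjusted over the list alone. For the LIF and STAT3 list camera gave adjusted p = 0.00299, and adjusted p = 0.518 with an estimated correlation. Tcfcp2l1 rose by 1.89 (SE 0.24), Klf4, a naive pluripotency factor, by 1.47 (SE 0.18), Lifr by 1.16 (SE 0.15) and Il6st, the shared gp130 receptor subunit, by 0.96 (SE 0.15). The falls were Ier3, an immediate early gene (-1.78, SE 0.39), and the adhesion molecule Icam1 (-0.68, SE 0.22), whose call ended without replicate 1 (adjusted p = 0.132), 2 (0.0881) or 3 (0.0737) of the labelled MLL4 knockdown and without wild type replicate 2 (0.0798) or 3 (0.0937). Of 21 p300/CBP and enhancer co-activator genes 5 rose and 0 fell, and 5 and 0 did so adjusted over the list alone. For the co-activator list camera gave adjusted p = 0.00629, and adjusted p = 0.701 with an estimated correlation. It gave 0.0712 without wild type replicate 2 and 0.0516 in lane 2 alone. Crebbp, the paralog of Ep300, rose by 1.00 (SE 0.28, adjusted p = 0.0225) and the bromodomain gene Brd9 by 0.58 (SE 0.15). The call of Crebbp ended without replicate 1 (adjusted p = 0.0587), 2 (0.0587) or 3 (0.0567) of the labelled MLL4 knockdown. Of 21 cholesterol biosynthesis genes 6 rose and 0 fell, and 7 and 0 did so adjusted over the list alone. For the cholesterol list camera gave adjusted p = 0.003, and adjusted p = 0.518 with an estimated correlation. The sterol desaturase gene Sc5d rose by 0.64 (SE 0.14).

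Of 24 S and G2/M cell cycle genes 5 rose and 1 fell in the libraries labelled MLL4 knockdown, and 5 and 1 did so adjusted over the list alone. For the cell cycle list camera gave adjusted p = 0.0127, adjusted p = 0.416 with an estimated correlation, and 0.0863 with the stricter filter on low counts. The mitotic genes Aurkb (0.47, SE 0.12) and Ccna2 (0.35, SE 0.10) rose and the replication helicase gene Mcm5 fell (-0.33, SE 0.10). Outside chromosomes 4, 8 and Y lay 0 falls of this list, so Mcm5 is a gene of those chromosomes. Without replicate 2 of the labelled MLL4 knockdown the adjusted p was 0.0724 for Aurkb, 0.0654 for Ccna2 and 0.0707 for Mcm5, without replicate 3 it was 0.0714, 0.0914 and 0.117, and without replicate 1 it was 0.0897 for Mcm5. Of 25 hypoxia and glycolysis genes 7 fell and 0 rose, and 8 and 1 did so adjusted over the list alone. For the hypoxia list camera gave adjusted p = 0.0127, and adjusted p = 0.701 with an estimated correlation. The hypoxia-induced genes Ndrg1 (-2.05, SE 0.40) and Ankrd37 (-1.45, SE 0.34) were among them, and the list gave 0.132 without replicate 1 of the labelled MLL4 knockdown and 0.0591 without wild type replicate 2. Of 11 2-cell-like genes 3 fell and 0 rose, and 3 and 0 did so adjusted over the list alone. For the 2-cell-like list camera gave adjusted p = 0.0447, and adjusted p = 0.701 with an estimated correlation. Zfp352, a zinc finger gene of the cleavage embryo, fell by 2.02 (SE 0.63) and Zscan4e by 1.69 (SE 0.54). Without replicate 2 of the labelled MLL4 knockdown their adjusted p was 0.138 and 0.14, without replicate 3 it was 0.123 and 0.135, without wild type replicate 1 it was 0.0662 and 0.158, and without wild type replicate 2 that of Zfp352 was 0.0689. The list call ended without replicate 2 (0.102) or 3 (0.102) of the labelled MLL4 knockdown, without wild type replicate 1 (0.192), with upper-quartile factors (0.0644) and with the transcript length trend removed (0.0989). All 3 measured Y-linked genes fell, and 3 did so adjusted over the list alone. For the Y-linked list camera gave adjusted p = 0.000889, and adjusted p = 0.416 with an estimated correlation. Ddx3y fell by 3.19 (SE 0.32), Uty by 3.83 (SE 0.28) and Eif2s3y by 4.96 (SE 0.61) to 3, 0 and 2 counts in replicates 1 to 3, so few that its fold change is uncertain.

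Several lists did not pass the list test in the libraries labelled MLL4 knockdown but held changed genes. Outside chromosomes 4, 8 and Y lay 3 of the 5 falls of core pluripotency genes and 4 of the 6 of interferon response genes. Of 16 core pluripotency genes 4 rose and 5 fell (4 and 6 adjusted over the list alone; adjusted p = 0.516), with Nanog at 0.67 (SE 0.12), the TGF-beta family ligand Gdf3 at 0.51 (SE 0.11) and the methyltransferase cofactor Dnmt3l at -2.84 (SE 0.20). Of 20 naive pluripotency genes 9 rose and 5 fell (10 and 6 adjusted over the list alone; adjusted p = 0.255), with Prdm14 at 1.46 (SE 0.15), Dppa3 at -3.26 (SE 0.22), the adhesion molecule Pecam1 at -1.79 (SE 0.14) and Fbxo15 at -1.21 (SE 0.13). Of 16 formative and primed genes 2 rose and 7 fell (3 and 7 adjusted over the list alone; adjusted p = 0.262), with Dnmt3b at -2.15 (SE 0.27), Dnmt3a at -1.10 (SE 0.17) and N-cadherin, Cdh2, at 1.13 (SE 0.19). Of 16 retinoic acid response genes 3 rose and 8 fell (4 and 9 adjusted over the list alone; adjusted p = 0.0599), with the retinoid carrier Crabp2 at -4.65 (SE 0.43), the meiotic gatekeeper Stra8 at -2.92 (SE 0.30) and the retinoid hydroxylase Cyp26a1 at -2.29 (SE 0.35). Of 19 primitive endoderm genes 7 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 0.0893), with the receptor Pdgfra at 2.59 (SE 0.23), the activin antagonist Fst at 2.48 (SE 0.22) and Gata6 at 1.52 (SE 0.29). Of 36 imprinted genes 5 rose and 8 fell (6 and 8 adjusted over the list alone; adjusted p = 0.996), with H19 at -5.85 (SE 0.47), Igf2 at -3.01 (SE 0.67), Grb10 at 1.73 (SE 0.13) and the zinc finger gene Plagl1 at 1.82 (SE 0.23). Igf2 stood at 19.9, 164 and 224 CPM in wild type replicates 1 to 3. In replicates 1 to 3 of the labelled MLL4 knockdown it stood at 17.2, 16.3 and 17.1 CPM. The size of this fall thus rests largely on wild type replicates 2 and 3. Of 13 feeder or fibroblast genes 1 rose and 8 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.113), with Tagln at -3.31 (SE 0.54). Of 14 interferon response genes 2 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.0629), with Oas1a at -3.28 (SE 0.47) and the RNA sensor Ddx58 at -1.28 (SE 0.17).

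In other lists of the same comparison, not all of which are given, Hox genes had 1 rise and 1 fall of 12 (1 and 1 adjusted over the list alone, camera adjusted p = 0.669). Nodal, TGF-beta and BMP targets had 3 rises and 5 falls of 17 (3 and 5 adjusted over the list alone, 0.428). FGF and ERK targets had 1 and 2 of 15 (1 and 2 adjusted over the list alone, 0.5). Extracellular matrix genes had 8 and 5 of 23 (9 and 5 adjusted over the list alone, 0.387). Mesendoderm and primitive streak genes had 0 and 3 of 14 (0 and 3 adjusted over the list alone; 0.421), and Wnt targets 3 and 1 of 13 (4 and 1 adjusted over the list alone; 0.387). Polycomb genes had 3 and 3 of 24 (4 and 3 adjusted over the list alone; 0.387), and other COMPASS and H3K27 demethylase genes 1 and 1 of 11 (1 and 1 adjusted over the list alone; 0.325). The p53 list had 3 rises and 5 falls of 19 (3 and 6 adjusted over the list alone; 0.637), and the cyclin-dependent kinase inhibitor Cdkn1a fell by 1.00 (SE 0.14). The MLL3/MLL4 COMPASS list had 4 rises and 1 fall of 10 (4 and 1 adjusted over the list alone; 0.113), the fall being the core subunit Ash2l (-0.82, SE 0.13), a gene of chromosome 8. The neuroectoderm list had 2 rises and 5 falls of 12 (2 and 6 adjusted over the list alone; 0.113), with Olig2, a factor of oligodendrocyte and motor neuron precursors, at 2.35 (SE 0.25) and Nes at -3.19 (SE 0.23), and 3 of its 5 falls lay outside chromosomes 4, 8 and Y. The adhesion gene Cdh1, E-cadherin, fell by 1.69 (SE 0.15). In total 3930 genes changed, of which 1592 rose and 2338 fell, and 373 rose and 1315 fell by more than 2-fold. The 3 libraries of one group lay wholly above those of the other for 42.9% of tested genes, against the 10% that chance gives. Lane 2 alone called 1341 genes, and without replicate 2 or 3 of the labelled MLL4 knockdown the count was 2273 or 2411.

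Set directly against the UTX knockout, the libraries labelled MLL4 knockdown had higher levels of the Nodal and BMP targets Lefty2 and Id3 and lower levels of the hypoxia genes Ndrg1 and Bnip3. Msc, a bHLH repressor, was higher by a log2 fold change of 5.18 (SE 0.35; 21.9 CPM ± 5.47 against 0.597 ± 0.163, SD, n = 3), Lefty2 by 3.55 (SE 0.46), Acta2 by 3.41 (SE 0.83), Emp1 by 3.34 (SE 0.47) and Sulf1, a heparan sulfate sulfatase, by 3.06 (SE 0.24). Oas3 was lower (-3.70, SE 0.25), as were Liph (-3.53, SE 0.15), Arhgap30, a GTPase activator (-3.48, SE 0.20), Gpx2 (-3.40, SE 0.39) and the epoxide hydrolase Ephx2 (-3.31, SE 0.24). The highest adjusted p among these 10 genes was 0.011, for Acta2. Of 17 Nodal, TGF-beta and BMP targets 9 were higher and 0 lower, and 9 and 3 were so adjusted over the list alone. For the Nodal list camera gave adjusted p = 0.00593, and adjusted p = 0.75 with an estimated correlation. Id3 was higher by 1.87 (SE 0.30), Ctgf by 1.69 (SE 0.14), Cyr61 by 1.21 (SE 0.10) and the inhibitory Smad7 by 1.08 (SE 0.14). Of 25 hypoxia and glycolysis genes 16 were lower and 0 higher, and 20 and 0 were so adjusted over the list alone. For the hypoxia list camera gave adjusted p = 5.64e-06, and adjusted p = 0.782 with an estimated correlation. Ndrg1 was lower (-2.50, SE 0.40), as were Aldoc (-1.77, SE 0.29) and the mitophagy receptor gene Bnip3 (-1.29, SE 0.24). Of 11 2-cell-like genes 2 were higher and 0 lower, and by edgeR 0 and 0 were so adjusted over the list alone, with 7 at an unadjusted p under 0.05. For the 2-cell-like list camera gave adjusted p = 0.00899, adjusted p = 0.782 with an estimated correlation, and 0.0562 without replicate 1 of the labelled MLL4 knockdown. The higher genes were Zscan4c (1.81, SE 0.62) and Gm13119, a PRAME family gene (1.86, SE 0.63). Without replicate 1 of the labelled MLL4 knockdown their adjusted p was 0.231 and 0.179, without UTX knockout replicate 2 it was 0.148 and 0.154, and without UTX knockout replicate 3 it was 0.137 and 0.123. Zscan4c also lost its call without UTX knockout replicate 1 (0.0552) or replicate 3 of the labelled MLL4 knockdown (0.0754), and Gm13119 without replicate 2 of the labelled MLL4 knockdown (0.0688). Of 15 FGF and ERK targets 4 were higher and 1 lower, and 5 and 1 were so adjusted over the list alone. For the FGF and ERK list camera gave adjusted p = 0.05, under the threshold before rounding, and adjusted p = 0.782 with an estimated correlation. This last call ended with the replicate block (0.0939), in lane 2 alone (0.0772), with a lane term (0.0534) and with RLE factors (0.0527). It ended too with the length trend removed (0.0593), with the stricter filter on low counts (0.128), and without replicate 2 (0.0518) or 3 (0.0573) of the labelled MLL4 knockdown or UTX knockout replicate 2 (0.0633). Spry2 was higher by 1.37 (SE 0.17) and Dusp6 by 0.97 (SE 0.14), while Ier3 was lower (-1.78, SE 0.39).

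The cholesterol list had 0 genes higher and 5 lower of 21 in this direct comparison (0 and 3 adjusted over the list alone; adjusted p = 0.138). Of 16 core pluripotency genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.441), with Gdf3 at 1.28 (SE 0.11), L1td1 at 0.93 (SE 0.13) and Dnmt3l at -2.36 (SE 0.20). Retinoic acid response genes had 1 higher and 6 lower of 16 (1 and 6 adjusted over the list alone; 0.0975) and interferon response genes 1 and 6 of 14 (1 and 7 adjusted over the list alone; 0.094). Of the 3 measured Y-linked genes 0 passed edgeR's test between these groups, by the adjusted p over all genes or over the list alone, and 0 had an unadjusted p under 0.05, with Uty at 0.24 (adjusted p = 0.595), Ddx3y at 0.17 (0.734) and Eif2s3y at -1.17 (0.312). In total 4275 genes differed, 1915 higher and 2360 lower in the libraries labelled MLL4 knockdown, and 555 and 1139 by more than 2-fold. The 3 libraries of one group lay wholly above those of the other for 52.6% of tested genes, against the 10% that chance gives. Lane 2 alone called 1535 genes, and the count was 2834, 2739 and 2793 without replicate 1, 2 or 3 of the labelled MLL4 knockdown, and 2556 and 2840 without UTX knockout replicate 2 or 3.

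Both comparisons with wild type asked which genes moved in the same direction when either protein was targeted. Krt8 (log2 fold changes -3.40, SE 0.63 in the UTX knockout and -3.40, SE 0.63 in the libraries labelled MLL4 knockdown) and Car4 (-4.16, SE 0.33 and -3.20, SE 0.31) fell in both. Thbs1 (-5.50, SE 0.67 and -3.20, SE 0.56) and Ddx3y (-3.36, SE 0.32 and -3.19, SE 0.32) did too. In wild type replicates 1, 2 and 3 Krt8 stood at 19.7, 211 and 170 CPM, and Thbs1 at 10.8, 52.6 and 78.8. The size of the Krt8 falls thus rests largely on wild type replicates 2 and 3, which both comparisons share. So does that of the Thbs1 fall in the libraries labelled MLL4 knockdown. In UTX knockout replicates 1 to 3 Thbs1 stood at 0.736, 1.47 and 0.882 CPM, well below wild type replicate 1 too. Genes that went opposite ways were Msc (-3.04, SE 0.35 and 2.13, SE 0.28), Arhgap30 (1.52, SE 0.18 and -1.96, SE 0.20) and Lrrc31 (1.42, SE 0.20 and -1.41, SE 0.22). Others were the class II antigen gene H2-Eb1 (1.13, SE 0.30 and -1.56, SE 0.33) and Lpar6, a lysophosphatidic acid receptor (-1.08, SE 0.23 and 1.21, SE 0.22). In the UTX knockout the call of H2-Eb1 ended without UTX knockout replicate 2 (adjusted p = 0.108) or 3 (0.0871) or wild type replicate 3 (0.0708), and that of Lpar6 without UTX knockout replicate 2 (0.0624). Of 1071 genes changed in both comparisons, 961 went the same way, 318 up and 643 down, and 110 opposite ways. Independent lists of these sizes would share 104 rises and 208 falls. The 3 wild type libraries cannot be split into parts of 2, so part of the excess of shared calls over these numbers may come from the shared controls. The same-way count was 41 in lane 2 alone, 467 and 557 without UTX knockout replicate 2 or 3, and 558 and 573 without replicate 2 or 3 of the labelled MLL4 knockdown. Across genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.473, against a mean of 0.501 in 30 simulations of unchanged groups sharing the wild type libraries. The covariance was 0.243 against a simulated 0.0382, a difference of 0.205. It was 0.117 with the stricter filter on low counts, 0.536 with DESeq2 and 0.695 with no filter, settings for which the shared controls were not simulated. The simulations gave all groups the same dispersion of a gene, although the wild type libraries differed most among themselves. The simulated covariance may therefore be too low, and the difference does not measure a shared response.

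**Figure D3:**
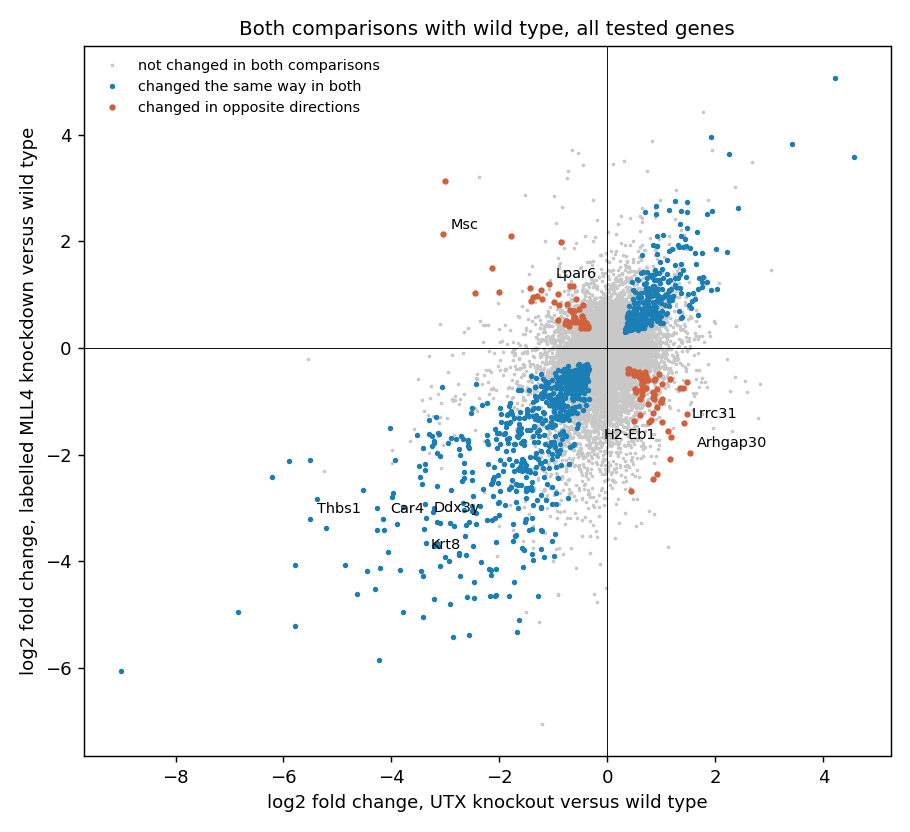
Log2 fold change of each tested gene in the UTX knockout (x axis) and in the libraries labelled MLL4 knockdown (y axis) against wild type, with the 9 genes named for both comparisons marked. Krt8 and Car4 lie low on both axes, and Msc lies at -3.04 on one and 2.13 on the other.

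Genes of chromosome 8 were lower as a group in both perturbed groups. Of 758 tested genes of this chromosome, 581 entered the tests by chromosome. Of these 239 fell and 6 rose in the UTX knockout (median log2 fold change -0.424, camera adjusted p = 3.07e-26, and adjusted p = 0.000216 with an estimated correlation). In the libraries labelled MLL4 knockdown 247 fell and 5 rose (median -0.374, camera adjusted p = 3.94e-15, and adjusted p = 0.00109 with an estimated correlation). Relative to autosomes other than 4 and 8, the median per library was -0.449 ± 0.025 (SD, n = 3) in the UTX knockout, -0.427 ± 0.016 in the libraries labelled MLL4 knockdown and 0.00195 ± 0.008 in wild type. On chromosome 4, of 720 genes used, a stretch of 270 neighbouring genes was chosen after the data were seen. It ran from Lyrm2 to Tesk2 in the gene order of the assembly GRCm38.p6. Its medians were -0.423 in the UTX knockout and -0.364 in the libraries labelled MLL4 knockdown, and those of the rest were 0.00413 and 0.000172. All 3 measured Y-linked genes fell in both comparisons too, and 0 of them passed edgeR's test between the perturbed groups. Such shifts shared by both perturbed groups cannot be separated from a difference of line or clone. The counts that follow were made over all tested genes. Outside chromosomes 4, 8 and Y, a count chosen after the data were seen, 1777 genes changed in the UTX knockout (920 up and 857 down) and 3282 in the libraries labelled MLL4 knockdown (1519 up and 1763 down), and 700 changed the same way in both.

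**Figure D4:**
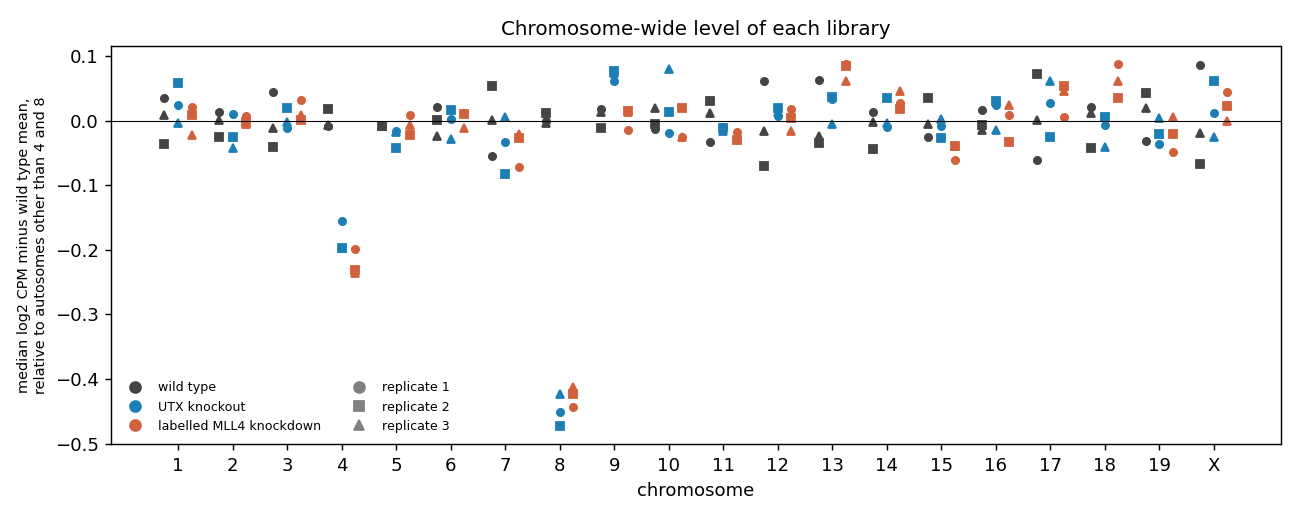
Median log2 CPM minus the wild type mean of the genes of each chromosome in each library (y axis), relative to autosomes other than 4 and 8, for the chromosomes on the x axis. The 6 perturbed libraries lie between -0.473 and -0.412 on chromosome 8, and the wild type libraries between -0.00416 and 0.011.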

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

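Removal of length and GC trends was chosen only after the results were seen. Genes changed in the UTX knockout numbered 750 at an adjusted p of 0.01, 335 with a minimum fold of 1.5, 74 in lane 2 alone, 1240 with only the 2 groups compared, 3446 with the replicate block, 4355 with the length trend removed and the replicate block, and 3808 with the GC trend removed and the replicate block, and 833 to 2854 without 1 library. Fewer libraries enter the lane 2 fit, and the cause of the other shifts was not tested. In the libraries labelled MLL4 knockdown they numbered 1895 at 0.01, 1138 with a minimum fold of 1.5, 1341 in lane 2 alone, and 2273 to 4108 without 1 library. Against the UTX knockout they numbered 2111, 1083 and 1535 under those settings, 6436 with the length trend removed and the replicate block, and 2556 to 4062 without 1 library. Genes changed the same way in both comparisons numbered 41 in lane 2 alone, 602 with only the 2 groups compared, 1473 with the replicate block, 1844 with the length trend and 1645 with the GC trend removed besides, and 467 to 1249 without 1 library. The Pearson correlation was 0.516 with DESeq2, 0.51 with no filter, 0.504 with the 2 groups alone, 0.412 with the stricter filter, and 0.468 to 0.527 without 1 library. The covariance was 0.536 with DESeq2, 0.695 with no filter, 0.117 with the stricter filter, and 0.261 to 0.319 without 1 library. Of the 93 list tests, 24 passed; 0 did with an estimated correlation, 37 with no filter, 14 with the stricter filter, and 21 to 25 without 1 library.

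The fold change of Kmt2d was -0.508 (adjusted p = 0.0213) with the length trend removed, -0.494 (0.00169) with the replicate block as well, and -0.507 to 0.159 without 1 library; that of Kdm6a was -2.48 in lane 2 alone and -2.45 to -2.12 without 1 library. Ep300 in the UTX knockout, at -0.06, turned to 0.0198 with limma-voom, 0.0201 without wild type replicate 1 and 0.198 without wild type replicate 3, with a lowest value of -0.32 without 1 library. Kmt2b there, at 0.05, turned to -0.00535 in lane 2 alone, -0.102 with the length trend removed, -0.0957 with the replicate block as well, -0.0326 without UTX knockout replicate 3 and -0.0908 without wild type replicate 2, with a highest value of 0.26 without 1 library. Ddx3y between the perturbed groups, at 0.17, turned to -0.097 in lane 2 alone and ranged from -0.0476 to 0.536 without 1 library. None of these passed the test, and the cause was not tested. Among the named genes and the lists, the replicate block changed no other call than those printed in the report. Of 183 calls of named genes, 86 ended in lane 2 alone, 7 with limma-voom, 5 with only the 2 groups compared, 2 with upper-quartile factors, 1 with DESeq2 and 1 with no filter, and none turned direction under any alternative.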

Other observations

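The tests of wild type replicates 2 and 3, of a lower share of another cell type, of the length trend in wild type replicate 2, of a mislabelled library and of divisions with each number once per group were chosen only after the result was seen.

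Single targets of Wnt signalling differed between the perturbed groups, while their list passed camera in no comparison. In the UTX knockout 2 of 13 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.615): the growth regulator Myc fell from 22.8 CPM ± 9.42 (SD, n = 3) to 8.07 ± 2.72, and the cyclin gene Ccnd1 fell by 0.64 on the log2 scale (SE 0.14). Without UTX knockout replicate 2 the adjusted p was 0.0587 for Myc and 0.0623 for Ccnd1, and without UTX knockout replicate 3 it was 0.0592 for Ccnd1. In the libraries labelled MLL4 knockdown Ccnd1 rose (0.69, SE 0.14), as did the Wnt feedback inhibitor Notum (2.13, SE 0.24) and the zinc finger gene Sp5 (2.10, SE 0.44), while the ubiquitin ligase gene Rnf43 fell (-1.80, SE 0.31). Set directly against the UTX knockout, Myc (1.84, SE 0.33), Ccnd1 (1.33, SE 0.14) and Sp5 (2.50, SE 0.45) were higher, with 4 of 13 targets higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.342). Single genes of protein stress differed too, and their list passed camera in no comparison. In the UTX knockout the chaperone gene Hspa5 rose by 0.57 (SE 0.14) and the stress factor Xbp1 by 0.66 (SE 0.11), while Chac1, a glutathione-degrading enzyme, fell by 1.63 (SE 0.20), with 3 of 20 genes of the list up and 3 down (3 and 3 adjusted over the list alone, camera adjusted p = 0.414). The call of Hspa5 ended without UTX knockout replicate 2 (adjusted p = 0.0825) or 3 (0.059) or wild type replicate 3 (0.0502). The stress factor Ddit3 fell by 1.73 (SE 0.41) in the libraries labelled MLL4 knockdown. Against the UTX knockout Ddit3 (-2.63, SE 0.42) and Hspa5 (-0.67, SE 0.14) were lower and Chac1 higher (1.44, SE 0.20), with 4 of 20 genes of the list higher and 6 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.989).

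Lower expression of chromosome 8 genes in both perturbed groups was seen across the expression levels of the 581 genes used. If fewer copies of the chromosome were present, each part of the expression range would be lower, and the medians over genes of low, middle and high mean expression were -0.444, -0.418 and -0.403 in the UTX knockout and -0.418, -0.338 and -0.334 in the libraries labelled MLL4 knockdown. Removing length and GC trends with the replicate block, which moved genes by a median of 0.0535 and 0.0754, left chromosome 8 at -0.443 and -0.437 relative to the other autosomes, against such a bias as the whole cause. A candidate explanation is a difference in copy number between wild type and both perturbed groups, which is a hypothesis, since DNA was not measured. Levels relative to wild type cannot tell fewer copies in the perturbed groups from more copies in wild type. Any biological effect of the perturbations was not tested separately.

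Keratin, trophectoderm and fibroblast genes were lower in both perturbed groups, with wild type replicate 1 nearer to them than replicates 2 and 3. Over all 28 measured members of the trophectoderm and feeder lists, the median of wild type replicates 1, 2 and 3 lay 0.33, 1.64 and 1.70 log2 CPM above the UTX knockout mean, and 0.448, 1.74 and 1.92 above the labelled MLL4 knockdown mean. The largest such median of 1 perturbed library against its group was 0.424 and 0.0972. A higher level in wild type replicates 2 and 3 alone cannot be told apart from a fall in the perturbed groups, because replicate 1 is a single library and lay no further from the UTX knockout than 1 of its own libraries. A lower share of 1 other cell type may account for part of it and cannot be told apart from a change in the stem cells, because the quartiles of the fallen members lay only 0.977 apart in the UTX knockout (-2.99 to -2.01) and further in the libraries labelled MLL4 knockdown (-3.31 to -1.82). The perturbation itself stays open.

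Kmt2d did not pass the test in the libraries labelled MLL4 knockdown. Wild type replicate 2 had median deviations from 0.31 in the shortest to -0.373 in the longest of 5 transcript length classes, and the longest Kmt2d transcript has 19823 nt. With the length trend removed and the replicate block, the log2 fold change was -0.494 (SE 0.0927, adjusted p = 0.00169), against -0.108 (SE 0.208, adjusted p = 0.719) with the block alone, so this trend may hide a fall. A mislabelling cannot be told apart from a weak knockdown: over the 1000 genes of highest variance each of these libraries correlated better with its own group than with another by a gap of at least 1, but 3 wrong labels would give the same agreement.

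Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real splits called 2285, 3930 and 4275 genes by edgeR, with 1 split as large in each comparison, the real one, and a highest other count of 0 in each (1746, 841 and 661 genes at an unadjusted p under 0.05). They called 12, 8 and 4 lists by camera, with highest other counts of 8, 8 and 10, and 1, 2 and 7 splits as large. Among splits that part all 3 pairs the highest other was 7, 6 and 7 lists. Every split but the real one mixes libraries of both groups, so the group difference widens the spread within each side. The highest other gene count of 0 therefore does not measure what chance gives. The 9 libraries divide into a control group and 2 others, with each replicate number once per group, in 108 ways. Of 100 such divisions drawn, 5 gave 961 or more genes changed the same way, the real one included, a share not under 0.05. The highest other gave 2093, and all 4 others had the libraries labelled MLL4 knockdown as the control group, so these counts carry the difference of that group. The share therefore speaks neither for nor against chance, which this test cannot exclude. Only the 12 divisions with an intact group as control gave any such gene. Without regard to the numbers, 2 of 100 divisions gave as many, the other with 1497.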
